A study of Saccharomyces cerevisiae with 202 samples.

How the data were processed

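The libraries came from yeast cultures sampled through 1 metabolic cycle. Per the labels, the RNA came from strain BY5765 (MATalpha, polyA RNA), the histone ChIP series from a MATa strain with tagged Spt7, and the modifier ChIP series from a MATa strain with tagged Gcn5 and Set1. Also per the labels, protein G beads were used for H3K9ac, H3K14ac, H3K56ac, H4K5ac, H3 and Gcn5, and protein A Sepharose for the other ChIP series. The submitters' processing notes name Bowtie for the libraries, TopHat in addition for the RNA, and the build sacCer2; versions are not given in the sources used here. The RNA values are the authors' deposited percent values, in 20 bp bins, in which the highest of the 16 libraries is 100 in every bin with signal. They carry no level, and depth, scaling between libraries, strand and the treatment of reads that map to several places are not given in the sources used here. The ChIP values are deposited signal in 100 bp bins, scaled by the authors to about the same total in all libraries of a series, as the totals show. No input or mock library was used here, and whether input was subtracted is not given in the sources used here.

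In 6 ChIP series, the low values of 87 libraries were whole multiples of 1 step near the library's smallest value (100.0% within a tolerance of 0.1). That percent covers low values only. Reads were recovered by dividing all values by the step. In the other series depth is unknown, except for H4K16ac at time point 1, where it was bounded by the size of the smallest value. A drift of the instrument or the culture over the time points cannot be told apart from the cycle, since 1 cycle was sampled once.

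Values were averaged in fixed 500 bp windows, and 1 was added before taking log2, which narrows the ranges of low windows. Fitted ranges are those of the curve, which can run past the values, so the widest RNA ranges are overstated. For RNA, windows needed at least 50% of their bins in the files and 80% of values above 0. For ChIP, windows needed a mean of at least 25% of the median window. Each series was fitted on its own with limma 3.58.1 (limma-trend) in R 4.3.3, with a natural cubic spline of 4 degrees of freedom over the time-point number and a moderated F test. A window counts as changed at a Benjamini-Hochberg adjusted p under 0.05 and a fitted range of at least 1 log2 (RNA) or 0.5 log2 (ChIP). Neighbouring windows are not independent, so counts of merged regions are given for RNA. Changed RNA windows were clustered by k-means with k = 3 (scikit-learn 1.9.0, 50 starts) on their scaled fitted curves. Mean profiles were tested with the spline F statistic against 100000 permutations of the time order, 2-sided in the sense that any shape counts, with Benjamini-Hochberg adjustment over 33 tests for the RNA clusters and over 11 for the chromosome ends. For the profiles and differences of the RNA clusters, in the alternatives on H3-corrected signal and without time point 1 the adjustment ran over fewer tests. Free permutation treats the time points as exchangeable, which neighbouring ones need not be. Any smooth drift of a mean profile can therefore give a small permutation p. Correlations were set against circular shifts of 1 mark. Introns were runs of intron bins (342 in the files, 217 with enough signal), tested with limma at an adjusted p under 0.05 and no minimum range. Reads recovered were also tested with edgeR 4.0.16 (quasi-likelihood F). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest.

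The tests, k = 3 and most alternatives had been fixed for genes before the data were examined, and were applied to windows instead. The gene table at hand follows assembly R64, not sacCer2, and its positions were not used for any value given. A trial placement of its genes on the bins was set aside, since it amounted to converting coordinates between builds. Gene lists, list mean profiles, a ribosomal protein intron mean and landmark genes were therefore not tested, and the intron mean covers all introns tested. Window length, filters and the added value of 1 were chosen once the file formats were known and before any fit. The windows named follow a rule fixed beforehand for genes: in each RNA cluster the 8 changed windows with the widest fitted range, and in each ChIP series the 3 widest with a mean above the median. For RNA, the level condition was replaced by signal above 0 in every bin and library, and neighbouring windows were not named again.

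The fits were tested on simulated data with 200 changed windows per series. Simulated ranges of 3 times the threshold were recovered in 97% (RNA, 21270 windows), 90% (H3K9ac, 23999), 100% (H3K56ac, 23994; H4K5ac, 23952; H3, 23634; H3K4me3, 22765), 97% (H3K36me3, 21253; Set1, 24001), 96% (Esa1, 24003), 88% (Gcn5, 24003), 79% (H3K14ac, 22645) and 42% (H4K16ac, 23568). Ranges of 1.5 times the threshold were recovered less often: in 72% for RNA, 17% for H3K9ac, 42% for H3K14ac, 80% for H3K56ac, 85% for H4K5ac, 15% for H4K16ac, 90% for H3, 74% for H3K4me3, 57% for H3K36me3, 14% for Gcn5, 30% for Set1 and 37% for Esa1. With only 200 changed windows, the cutoff after adjustment is stricter than in series where many windows changed, so these rates can understate recovery there. Recovery in the real series is therefore unknown, and shares of changed windows are not to be compared between series for small changes. Of simulated noise profiles, 5.35% had a permutation p under 0.05. That noise had no dependence between neighbouring time points. Alternatives tried were a spline of 3 degrees of freedom, 2 harmonics, centring on each library's median window, another pseudocount, no filter, no minimum range, signal relative to H3, k = 4, rank correlation and leaving out each time point.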

Results

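The series followed budding yeast (Saccharomyces cerevisiae, CEN.PK background) through 1 yeast metabolic cycle, the oscillation in oxygen consumption that such cultures show in continuous growth. Of the 202 libraries, 186 in 12 series were analysed here: polyA RNA-seq at 16 time points, ChIP-seq of H3 and of 7 H3 or H4 modifications at 16 time points, and ChIP-seq of Gcn5, Set1 and Esa1 at 14 time points. Gcn5 and Esa1 are histone acetyltransferases and Set1 is the H3K4 methyltransferase. A second H3K9ac series of 16 libraries, sampled with the RNA, was not analysed here. Each time point was 1 library, so there were no replicates, and the error of every value below is the scatter of the libraries about a smooth curve over time. The RNA, the histone series and the 3 modifier series came from different strains. Time-point numbers are therefore not comparable between these 3 sets, and hours were not given. Signal was compared in 24139 windows of 500 bp on the 16 nuclear chromosomes, in sacCer2 coordinates. The windows carry no gene names.

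Depth could be recovered for 6 ChIP series, in which the low deposited values were whole multiples of 1 read. H4K5ac was the deepest, with 10724106 to 20025120 reads in 15 libraries. The H3 libraries held 2954923 to 7361114 reads and the H3K4me3 libraries 1758311 to 7642501. Gcn5 libraries held 2035634 to 11077142 reads, Set1 2527021 to 11822357 (13 libraries) and Esa1 2236609 to 11020818 (13 libraries). The depth of the RNA and most other libraries is unknown. The exception was H4K16ac at time point 1, whose smallest value is so large that the library holds about 24047 to 24182 reads, with 46.1% of tested windows at 0.

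The first question was how much of the transcribed genome changed over the cycle. RNA signal changed in 12637 of 21270 tested windows (59.4%), which formed 3379 separate regions. The median fitted range was 1.63 log2, against a median residual SD of 0.38, both over the changed windows. The largest fitted range, 7.25 log2, is more than percent values can span once 1 is added, so the curve ran past the values there. The windows that changed fell into 3 clusters by the shape of their curves. Cluster 1 (3846 windows in 1346 regions) was high at the start and end of the series, with a mean of 67.8% of each bin's own maximum at time point 1, 21.8% at time point 5 and 70.9% at time point 13. Cluster 2 (5188 windows in 1759 regions) did the opposite, with 79.5% at time point 4 and 21.6% at time point 13. Cluster 3 (3603 windows in 1391 regions) was high in the middle, with 76.7% at time point 8 and 31.8% at time point 16. The clusters were formed from the same data, so their separation is not itself tested. With k = 4, cluster 3 divided into groups that shared 1812 and 1791 of its windows, the former a group of 2169 and the latter a group of 3149 that also took 1358 windows of cluster 2.

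**Figure D1:**
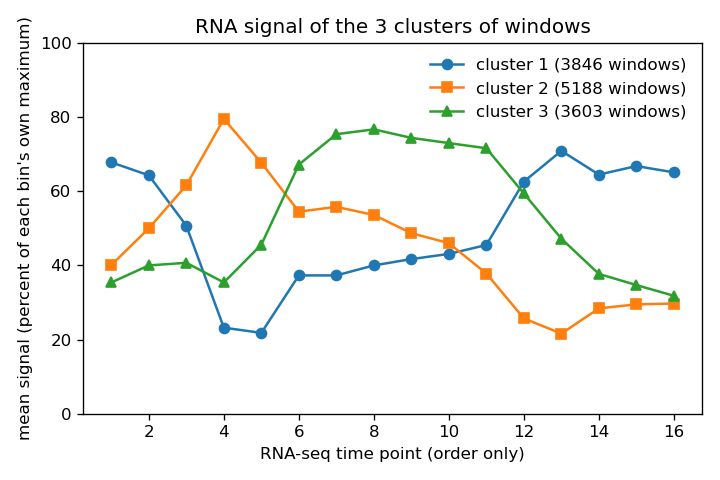
Mean RNA signal of the windows in each cluster (vertical axis, percent of each 20 bp bin's own maximum) against RNA-seq time point (horizontal axis, order only). Each point is 1 library, averaged over the 3846, 5188 or 3603 windows of the cluster. Cluster 2 is highest at time point 4 (79.5%), cluster 3 at time point 8 (76.7%) and cluster 1 at time point 13 (70.9%).

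The windows described next are those with the widest ranges in each cluster among windows with RNA signal above 0 in every bin and library, 1 per region. The fitted ranges were widest in cluster 1. In all 8 windows named there the fitted range exceeded that of the window's own values with 1 added, since the curve ran past them. The same held for most windows named in cluster 3. On chromosome XVI, the window at 128501 to 129000 went from 99.9% at time point 1 to 0.5% at time point 7, a fitted range of 7.25 log2 (residual SD 0.73, limma adjusted p = 1.5e-06). The windows at XVI 18001 to 18500 and XV 1072001 to 1072500 had fitted ranges of 7.11 and 7.1 log2, and both were highest at time point 13, at 97.3% and 98.8%. The windows at III 132501 to 133000, XIII 483001 to 483500, VII 655501 to 656000, II 474501 to 475000 and I 44501 to 45000 had ranges of 6.61, 6.56, 6.54, 6.53 and 6.47 log2. In cluster 2, the window at IV 47001 to 47500 stood at 100.0% at time point 7 and 1.1% at time point 14, a fitted range of 4.83 log2 (residual SD 0.4, limma adjusted p = 3.6e-06). Windows at VIII 287501 to 288000, XV 957001 to 957500, VII 807001 to 807500 and XIV 360001 to 360500 followed, with 4.66, 4.46, 4.21 and 4.04 log2, and all but the first were highest at time point 4. The other cluster 2 windows with wide ranges lay at XII 814001 to 814500 (4.03 log2), XIV 714001 to 714500 (3.99 log2) and XV 68001 to 68500 (3.95 log2). In cluster 3, the window at IV 1079001 to 1079500 had the widest range of these, from 98.0% at time point 5 to 1.5% at time point 16 (4.99 log2, residual SD 0.53, limma adjusted p = 2.6e-06). The window at II 236501 to 237000 followed its curve most closely among those named, rising to 100.0% at time point 9 and standing at 3.8% at time point 16, with a residual SD of 0.22 and a range of 4.71 log2. Others of cluster 3 were XIII 879501 to 880000 (4.89 log2), XIV 13501 to 14000 (4.55 log2), VI 11501 to 12000 (4.48 log2), X 443001 to 443500 (4.46 log2), IV 445001 to 445500 (4.43 log2) and XV 798001 to 798500 (4.3 log2). Since each bin is expressed against its own maximum, these ranges are of relative change and say nothing of level.

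The intron files allowed intron signal to be set against the 200 bp of non-intron signal on either side. Of 217 introns tested, 35 changed relative to their flanks at an adjusted p under 0.05 with no minimum range, with a median fitted range of 1.43 log2; 33 of them had a range of at least 1 log2. In 13 of the 35 the fitted ratio was highest at time point 1 and in 10 at time point 16, and in 12 it was lowest at time point 12. Among all 217 introns it was also most often highest at time point 1 and next at time point 16. That peak timing is therefore not particular to the changed introns. The mean over all 217, the 35 included, went from 0.28 log2 above its average at time point 3 to -0.22 at time point 11 (fitted range 0.43 log2, permutation p = 0.0011). Intron and flank are each scaled to their own maxima, so the ratio compares shapes over time and not the share of unspliced RNA.

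The chromatin series asked which histone marks move with the cycle, and they differed widely. H3K56ac changed in 19918 of 23994 windows (83.0%) and H3K9ac in 17068 of 23999 (71.1%), with median fitted ranges of 0.82 and 1.12 log2. H4K5ac changed in 6810 of 23952 (28.4%) and H3K14ac in 4919 of 22645 (21.7%). The methyl marks moved in fewer windows, H3K4me3 in 2451 of 22765 (10.8%) and H3K36me3 in 1551 of 21253 (7.3%). H3 itself passed in 301 of 23634 (1.3%), but 5 of 100 orders of its time points, the real one included, gave at least as many windows (highest other 466), so chance is not excluded for H3. Differences between the shares were not tested, and they depend on residual scatter. Over the changed windows only, the median residual SD was 0.15 (H4K5ac) to 0.26 (H3K9ac) in these 7 series. It does not give the scatter of all tested windows. H3K9ac and H3K56ac also had the widest spread of library medians, 0.5 and 0.4 log2. In the other ChIP series it was 0.04 to 0.35 log2, and the threshold was 0.5 log2. The shares therefore cannot be read as a ranking of the marks by their response to the cycle. The H3K36me3 count was 648 without time point 7 and 4833 without time point 1, and the H3K14ac count was 8375 without time point 15. Relative to H3, the counts were 358 for H3K36me3, 1062 for H3K4me3 and 3011 for H3K14ac. The H4K5ac count was 4081 with a spline of 3 degrees of freedom and 11962 with no minimum range, and without a minimum range the H3K4me3 count was 3856.

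H4K16ac changed in 13837 of 23568 windows (58.7%), with a median fitted range of 3.53 log2. This count rested on single libraries and on the form of the curve. Without time point 1, the library of about 24047 to 24182 reads, 2182 windows passed, and without time point 4 only 1 did. With 2 harmonics in place of the spline, limma passed 0 windows (lowest adjusted p = 0.34), with 1264 at an unadjusted p under 0.05. Its widest named windows, XIV 1501 to 2000, V 574501 to 575000 and III 92001 to 92500, were all listed at 0.0 at time point 1.

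**Figure D2:**
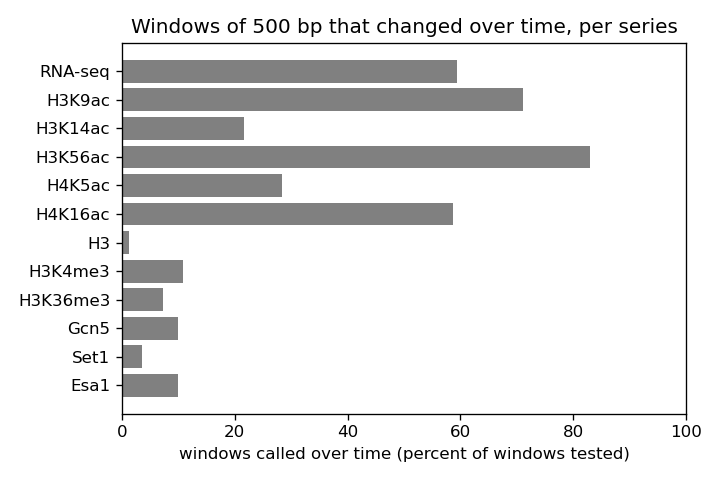
Percent of tested 500 bp windows that changed over time (horizontal axis) in each of the 12 series (vertical axis), 1 bar per series. H3K56ac has the longest bar (83.0%) and H3 the shortest (1.3%); the H4K16ac bar (58.7%) includes time point 1.

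The regions named next are, for each series, the 3 widest among changed windows whose mean signal was above the median, 1 per region. With lower signal included, the largest ranges were 2.89 log2 for H3, 3.45 log2 for H3K36me3 and 2.58 log2 for H3K4me3, wider than any named for these marks. Within that limit, H3K9ac ranged most at V 265001 to 265500, from 19.4 at time point 8 to 431.4 at time point 15 in deposited signal (fitted range 4.14 log2, limma adjusted p = 1.1e-08). It ran the other way at V 270001 to 270500, 5 kb along, with 481.0 at time point 4 and 17.0 at time point 12 (3.94 log2), and at XI 109001 to 109500 (3.93 log2, highest at time point 4). H3K56ac was widest at XI 21501 to 22000, from 193.6 at time point 4 to 5.8 at time point 11 (3.64 log2, limma adjusted p = 4.8e-16), then at IV 1162001 to 1162500 (3.11 log2) and IV 679501 to 680000 (2.96 log2), both also highest at time point 4. H3K14ac was widest at VII 228001 to 228500 (2.43 log2), VII 108001 to 108500 (2.1 log2) and XVI 405001 to 405500 (1.94 log2). For H4K5ac the widest were X 356001 to 356500 (1.86 log2), II 117501 to 118000 (1.59 log2) and XII 439501 to 440000 (1.51 log2). The 3 H3K4me3 windows so chosen were all on chromosome XV, at 988501 to 989000 (2.4 log2), 161001 to 161500 (2.39 log2) and 836501 to 837000 (1.97 log2), and all were lowest in the fit at time point 8. Under the same limit H3K36me3 was widest at II 451001 to 451500, from 14.6 at time point 1 to 83.0 at time point 6 (2.35 log2), at XII 811001 to 811500 (1.9 log2) and at XI 383501 to 384000 (1.84 log2). Among windows above the median signal, H3 ranged most at XV 1040001 to 1040500, from 29.3 at time point 11 to 69.1 at time point 8 (1.08 log2, limma adjusted p = 8.6e-06), then at VII 481501 to 482000 (0.88 log2) and XII 639501 to 640000 (0.85 log2).

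Of the modifiers, Gcn5 changed in 2405 of 24003 windows (10.0%), Esa1 in 2389 of 24003 (10.0%) and Set1 in 849 of 24001 (3.5%), with median ranges of 1.13, 0.98 and 1.07 log2. By the same choice of windows, neighbours on chromosome II carried the widest ranges of Gcn5 and Set1. Gcn5 rose from 46.7 at time point 5 to 864.9 at time point 10 at 381501 to 382000 (fitted range 3.66 log2, residual SD 0.69, limma adjusted p = 1.8e-05). Set1 stood at 42.7 at time point 6 and 667.0 at time point 11 at 382001 to 382500 (fitted range 3.58 log2, residual SD 0.76, limma adjusted p = 0.0003). The Set1 curve was highest at time point 1, so its fitted range is not that of these values. At chromosome XV, 1039501 to 1041000, all 3 modifiers had 1 of their 3 named windows, with 3.51 log2 for Gcn5, 3.48 for Set1 and 2.42 for Esa1. Scatter about these curves was wide, with residual SDs of 0.75, 1.1 and 0.74. The first H3 window named above lies there too, but H3 ranged more in windows of lower signal. Other wide windows were V 264501 to 265000 for Gcn5 (3.5 log2), VI 107501 to 108000 for Set1 (3.37 log2), and II 419501 to 420000 (2.76 log2) and XI 23501 to 24000 (2.72 log2) for Esa1. The Set1 count was 545 without time point 5, and the Esa1 count was 1392 without time point 7 and 1576 without time point 10. Esa1 gave 955 windows with a spline of 3 degrees of freedom, and Set1 gave 1475 with 2 harmonics and 1401 in windows of 1000 bp, a length chosen after seeing the data.

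The next comparison asked whether the RNA clusters differ in their chromatin over time. Of 33 profiles of a cluster's mean signal against all tested windows, 28 changed over time after adjustment. With a spline of 3 degrees of freedom, 5 of these no longer passed: H4K5ac over clusters 1 and 2 (adjusted p = 0.7 and 0.27) and Gcn5, Set1 and Esa1 over cluster 3 (0.36, 0.2 and 0.27). The changes in the mean were small beside those of single windows. H3K36me3 over cluster 1 was 0.169 log2 above the average of all windows at its highest and 0.066 log2 below at its lowest (fitted range 0.249 log2, highest at time point 1 and lowest at time point 8, permutation adjusted p = 0.00016). Over cluster 2 it was above average throughout, by 0.183 to 0.364 log2, and was highest at time point 8 (adjusted p = 6.6e-05). H3K4me3 ran in the same opposite senses, highest at time point 1 over cluster 1 (range 0.151 log2) and at time point 8 over cluster 2 (range 0.125 log2). H3K9ac over cluster 1 ranged by 0.279 log2 (adjusted p = 0.016), while over cluster 2 its change did not pass (adjusted p = 0.19). H3K14ac over clusters 1 and 2 (adjusted p = 0.057 and 0.43) and H3 over clusters 1 and 2 (adjusted p = 0.3 and 0.21) did not pass either.

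Differences between clusters were tested directly. Of 33 differences, 28 changed over time. In alternatives chosen after seeing the data, 6 of the 28 did not pass with a spline of 3 degrees of freedom: all 3 for H4K5ac (permutation adjusted p = 0.79, 0.68 and 0.84), H3 between clusters 2 and 3 (0.36), H3K14ac between clusters 1 and 3 (0.051) and H3K56ac between clusters 2 and 3 (0.051). The last did not pass relative to H3 either (0.097). The 3 H4K16ac differences passed without time point 1 (1.5e-05, 1.5e-05 and 0.00059). The widest were between clusters 1 and 2: 0.495 log2 for Gcn5 (permutation adjusted p = 0.0095), 0.416 for H3K36me3 (4.7e-05), 0.399 for Set1 (0.0041) and 0.318 for Esa1 (0.0098). For Gcn5 the difference went from -0.269 to 0.433 log2, in favour of cluster 1 around time point 11 and of cluster 2 around time point 5. H3K9ac differed between clusters 1 and 3 (0.307 log2, adjusted p = 0.0046), and its wider fitted range between clusters 1 and 2, 0.403 log2, did not pass (adjusted p = 0.087). The smallest p that these 100000 permutations can give is 1e-05. They treat time points as exchangeable, so a smooth drift of any origin can also pass.

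Marks sampled at the same times were then compared with each other. H3K9ac and H3K56ac had a median Pearson r of 0.49 over 22306 windows that changed in either mark (median Spearman rho 0.48), and 0.43 without the 2 time points farthest from the H3K9ac median in each window. H3K14ac and H4K5ac had 0.44, and H3K9ac and H3K14ac 0.42. The highest values after shifting the time points of 1 mark were 0.46, 0.51 and 0.42 for these 3 pairs, and in only 4 of 28 histone pairs was every shifted value lower. H3K4me3 and H3K36me3 had a median r of 0.24 (highest shifted 0.26). Among the modifiers, Gcn5 and Esa1 had a median r of 0.6, Gcn5 and Set1 0.54, and Set1 and Esa1 0.42, with highest shifted values of 0.49, 0.43 and 0.36. Their median Spearman values were 0.56, 0.49 and 0.39. The shifts cannot give a p under 0.0625 for the histone pairs or 0.0714 for the modifier pairs, so none of these 31 relations could pass a threshold of 0.05.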

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

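The alternatives weighed in this part were planned, but their use as tests of these explanations, and the other time orders, were chosen after the results were seen. The ChIP libraries held signal outside the nuclear chromosomes, which no comparison above uses, and there was no control library to set it against. The median share of a library's signal on the mitochondrial chromosome was 0.792% for H3K9ac, 0.38% for H3K14ac, 0.299% for H3K56ac, 0.56% for H4K5ac, 0.047% for H4K16ac, 0.065% for H3, 0.046% for H3K4me3 and 0.014% for H3K36me3. It was 1.238% for Gcn5, 2.529% for Set1 and 1.442% for Esa1. On the 2 micron plasmid the median share was 3.006% for H3K9ac, 2.032% for H3K56ac, 2.532% for H4K5ac, 1.573% for H4K16ac, 1.442% for H3, 1.731% for H3K4me3, 1.218% for H3K36me3, 5.402% for Gcn5, 5.616% for Set1 and 5.456% for Esa1.

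The number of H4K16ac windows that changed, 13837, may be set by the low depth of its first library. Without time point 1, 2182 windows passed, of which 1615 were among the 13837. Leaving out time point 4 left 1 window, so the count depended on that library as well. That fit still held time point 1 and no fit left out both. Only time point 1 is known to be shallow, with 46.1% of tested windows at 0. Depth at time point 4 is unknown, so how far each library set the count cannot be told apart. No biological explanation was tested.

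H3K9ac and H3K56ac changed in most of the genome. Scaling each library to a common total could produce such a spread, but after centring each library on its median window 15141 H3K9ac and 17464 H3K56ac windows passed, of which 12780 and 16335 had passed before. A change in nucleosome occupancy as measured by H3 was also tested, and on signal relative to H3 16162 and 19559 windows passed, of which 15352 and 18525 had passed before. The counts after centring argue against a single offset per library as the whole cause. Centring cannot remove a change in contrast between high and low windows under a fixed total. The H3K9ac library medians ran from 27.4 at time point 4 to 39.2 at time point 12. Time point 12 was also the commonest fitted peak of its changed windows (3904). H3 itself passed in only 1.3% of windows, so taking it off could lower these counts little. That comparison could therefore hardly have come out otherwise. What the values show is only that H3 as measured here passed in too few windows to carry most of these changes. A technical drift over the time points stays open, as does the cycle itself.

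Whether chance order of the libraries gives as many changed windows was asked with 100 orders per series, the real one included. The real order alone gave its count (1 of 100) in 11 series. The highest other count was 3301 for RNA (real 12637), 4046 for H3K9ac (17068), 2502 for H3K14ac (4919), 10198 for H3K56ac (19918), 516 for H4K5ac (6810), 12574 for H4K16ac (13837), 430 for H3K4me3 (2451), 785 for H3K36me3 (1551), 1336 for Gcn5 (2405), 239 for Set1 (849) and 1991 for Esa1 (2389). For H3, 5 of 100 orders gave at least 301 windows, with a highest other count of 466, so chance is not excluded there.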

How the results depend on the processing

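Some alternatives were chosen after seeing the data. They were windows of 1000 bp, edgeR on reads, and the H4K16ac profiles without time point 1, of the clusters and of the chromosome ends. The correlations without 2 time points, all alternatives for the differences between clusters and the chromosome ends with k = 4 were also chosen then. The other alternatives were planned. Of 500 alternatives, 446 kept the result on its side of the threshold or within 1.5 times its count (for correlations, within the SD of the shifted values), and 54 did not. All alternatives run for the RNA, H3K9ac, H3K56ac, H3 and Gcn5 counts stayed within 1.5 times. A count within that limit need not hold the same windows. For H3, 249 windows lay in a changed window of 1000 bp, of which 142 were among the 301. For H3K14ac the count of 4919 was 3143 with no filter and 3011 relative to H3. For H4K5ac (6810) it was 4081 with 3 degrees of freedom and 11962 with no minimum range. For H4K16ac (13837), limma with 2 harmonics passed 0 windows, with 1264 at an unadjusted p under 0.05. H3K4me3 (2451) gave 3856 with no minimum range and 1062 relative to H3. H3K36me3 (1551) gave 2467 with 3 degrees of freedom, 2388 with 2 harmonics and 358 relative to H3. Set1 (849) gave 1475 with 2 harmonics and 1401 in windows of 1000 bp, and Esa1 (2389) gave 955 with 3 degrees of freedom. With k = 4, the group sharing most windows with cluster 3 (1812) held 2169 windows, and a group of 3149 shared 1791. With 3 degrees of freedom the profiles of H4K5ac over clusters 1 and 2 had adjusted p = 0.7 and 0.27, and those of Gcn5, Set1 and Esa1 over cluster 3 had 0.36, 0.2 and 0.27. Differences between clusters had adjusted p = 0.79, 0.68 and 0.84 (H4K5ac), 0.36 (H3, clusters 2 and 3), 0.051 (H3K14ac, clusters 1 and 3) and 0.051 (H3K56ac, clusters 2 and 3) with 3 degrees of freedom, and 0.097 (H3K56ac, clusters 2 and 3) relative to H3. Correlations near 0 moved: after centring, H3K14ac with H4K16ac -0.05, H3K56ac with H4K16ac -0.01, H3K56ac with H3K36me3 -0.05, H4K16ac with H3K4me3 0.01 and with H3K36me3 -0.03; by Spearman, H4K5ac with H4K16ac -0.08, H4K16ac with H3 0.06 and with H3K4me3 0.04; without the 2 farthest time points, H4K16ac with H3 0.07, with H3K4me3 0.06 and with H3K36me3 -0.03. Leaving out single time points gave 3715 to 8375 for H3K14ac (8375 without 15), 1 to 16689 for H4K16ac (1 without 4, 2182 without 1), 648 to 4833 for H3K36me3, 545 to 1067 for Set1 (545 without 5) and 1392 to 2630 for Esa1 (1392 without 7, 1576 without 10). For H3K36me3 the time points concerned were 1 (4833), 2 (2641), 4 (2948), 5 (780), 7 (648), 8 (902), 9 (757), 10 (787), 11 (899), 13 (838) and 15 (907). The cause was not tested in any of these. The H4K16ac profiles passed without time point 1, with adjusted p = 1.5e-05, 0.0011 and 1.5e-05 for clusters 1 to 3. On recovered reads edgeR passed 7374 windows for H4K5ac, 345 for H3, 2788 for H3K4me3, 2237 for Gcn5, 1206 for Set1 and 1925 for Esa1. Signal over the whole gene, list mean profiles and centring of lists were not run, since no gene positions were used. Where depth is unknown its effect could not be assessed.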

Other observations

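The overlap counts, the ChIP profiles of chromosome ends and the k = 4 count at the ends were chosen after the data were seen; the rule for the RNA windows at chromosome ends was written before its result. Windows that changed in RNA and in chromatin coincided more often than independent lists would for 9 of the 11 ChIP series. Set1 had 733 windows changed in both against 462 for independent lists, H3K36me3 1205 against 873, H3K4me3 1626 against 1239, Gcn5 1438 against 1102, H3K14ac 3064 against 2462 and H4K5ac 4008 against 3352. H3 had 186 against 144, Esa1 1166 against 960 and H3K9ac 9226 against 9056. None of 1000 rotations of the changed windows along the genome gave as many in these 9. For H3K56ac (10608 against 10563) 92 of 1000 rotations did, and for H4K16ac (7286 against 7293) 554 did. H3 was among the 9 although chance order was not excluded for its calls. Such an overlap therefore does not show that a series follows the cycle. The rotations did not match windows for signal level.

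Changed RNA windows within 10 kb of chromosome ends may share a timing more than others do. Of 266 changed RNA windows there, 47.0% were in cluster 3 against 28.1% elsewhere, while cluster 1 held 18.0% against 30.7% and cluster 2 35.0% against 41.2%. As large an excess arose in a share of 0.0029 of 10000 rotations of the cluster labels along the genome. With k = 4 the end windows also concentrated in 1 group (73.3% against 23.9%, share of rotations 0.0003), but that group drew 1791 windows from cluster 3 and 1358 from cluster 2, while the group sharing 1812 windows with cluster 3 was rarer at the ends (9.0% against 17.3%). The concentration therefore held under both, but its assignment to cluster 3 as a whole did not. Reads shared between the repeated sequences of chromosome ends were not examined, and they stay open as a source.

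Chromatin signal at the same ends, relative to the interior, also changed over time in some series. Ends and interior differed in mean level, by -0.22 log2 for H3K9ac and 0.11 log2 for H3K56ac. A change in contrast over a whole library could therefore move these differences too. Neither signal relative to H3 nor reads shared between repeated sequences were examined here. H3K56ac at the ends, relative to the interior, went from -0.38 log2 at time point 9 to 0.46 log2 at time point 15 (fitted range 0.74 log2, permutation adjusted p = 0.00011), and H3K9ac from -0.61 at time point 8 to 0.02 at time point 13 (range 0.45 log2, adjusted p = 0.0042). H4K5ac, H3K14ac, H4K16ac and Gcn5 changed by 0.3, 0.29, 0.22 and 0.17 log2 (adjusted p = 0.0067, 0.0059, 0.0071 and 0.0096). The H4K16ac profile was highest at time point 1 (0.41), the library of about 24047 to 24182 reads; without it the range was 0.17 log2 (adjusted p = 0.0096). H3K14ac was measured in 180 end windows, against 484 to 602 in the other series. H3, H3K4me3, H3K36me3, Set1 and Esa1 did not pass, with ranges of 0.09, 0.07, 0.09, 0.14 and 0.08 log2 and adjusted p = 0.4, 0.54, 0.4, 0.3 and 0.4.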
